A study of Mus musculus with 6 samples.

How the data were processed

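RNA sequencing of mouse femurs was available as 1 table of FPKM values with gene coordinates, lengths and biotypes. Per the labels' protocols, femurs were frozen, ground and extracted for total RNA, and libraries were sequenced by a commercial provider. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, STAR and featureCounts and the genome build was mm10. Versions, settings, strandedness and the gene annotation are not given in the sources used here. The authors deposited FPKM values, 1 per gene and library, with 1 length per gene. How they computed FPKM is not given in the sources used here, and tested on the values it was reads divided by the listed gene length and by 1 total per library. The series' design text also states that the authors used DESeq2 and limma with an absolute log2 threshold of 0.2, which were not rerun.

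A column was used only where its name matched the library name of 1 sample in the labels. This held for 3 columns, the OVX replicates 1, 2 and 3. The names of the other 3 columns of values matched no label, and these columns were not used here. All comparisons of zingerone with OVX, planned with limma on log2(FPKM + 1) before the data were examined, were therefore not run. The same holds for the planned gene set tests, the authors' threshold and the part of the rule for named genes that ranks genes by that comparison. The series' design text calls the samples biological replicates, while no label names separate animals, so the SD measures the spread between these libraries, which may in part be technical.

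For each library, FPKM multiplied by gene length was a whole multiple of 1 step for 100% of values, within 0.01 read, which gave the reads per gene. The reads listed came to 17017907, 16964740 and 16581579 in libraries 1, 2 and 3. The totals behind the authors' FPKM were 17279919, 16845977 and 16533661, or 1.02, 0.993 and 0.997 times the reads listed. FPKM of library 1 are thus slightly lower than its reads listed would give. The FPKM themselves were level, with median-of-ratios factors of 1.0021, 1.0019 and 1.0017 in libraries 1, 2 and 3. The chi-square test described below used the reads listed, so this small difference in scale enters it. A count of 0 allows up to 3 reads, or 1.76e-05%, 1.77e-05% and 1.81e-05% of reads. Intervals are at 95%, exact Poisson for FPKM and exact Clopper-Pearson for shares of reads. They cover counting error only, since reads without molecular identifiers are not independent molecules.

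Genes with a mean of at least 1 FPKM over the 3 libraries were tested. Reads per gene were compared between libraries by a chi-square test against the library totals, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log values are log2(FPKM + 1), a scale that understates differences of low genes. For each gene list the shift is the median over tested members of the value in 1 library minus the mean of the other 2. Its percentile was taken among 10000 random lists of the same size drawn within 50 bins of mean expression. Genes of a list are co-expressed, so such percentiles are more extreme than independent genes would give. These comparisons between libraries, the 2-fold count and the genes named beyond Sat1, Gpx4 and Trp53 were chosen after the values had been seen.

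The 30 gene lists were fixed before the data were examined. They cover the title genes, ferroptosis promotion and restraint, p53 targets, polyamine metabolism, iron handling, antioxidant genes, 14 cell type lists, proliferation, inflammation, interferon response, sterol and lipid synthesis, Wnt signalling, oxidative phosphorylation, immediate early genes, mitochondrially encoded genes and sex-linked genes. Of 510 symbols, 503 were in the table. Lists of growth plate, joint surface and tendon genes were added after the shares of the fixed lists had been seen. Of 54532 gene identifiers, 54495 occurred in GENCODE release M21 and 53585 had the same start and end there, including all 3 title genes.

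On simulated data with the real library totals, in which 200 of the 14011 genes were raised in library 2, the chi-square test found 82% of genes raised 1.5-fold and 90% of those raised 2-fold, and called 0.152% of unchanged genes. Of 100 simulated lists of unchanged genes, 3 lay outside the central 99% of random lists. The simulated counts were Poisson, with no other variation between libraries, and list genes were drawn independently. These rates therefore hold for counting noise alone and not for co-expressed genes of the real libraries. Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, 3 other scalings, FPKM recomputed from the reads listed, and each library left out. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.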

Results

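Femoral RNA of ovariectomized mice (OVX), a model of bone loss after the menopause, was measured by RNA sequencing. The labels give 6 samples in 2 groups of 3, namely OVX mice given saline and mice given zingerone, a phenolic compound of ginger, by mouth at 100 mg/kg per day for 8 weeks. The values of 3 libraries could be tied to their labels, all from the OVX group with saline, and are reported as libraries 1, 2 and 3 after their replicate numbers. The zingerone libraries were not analysed here, since no column of the table carried their names, so the effect of zingerone on Sat1, Gpx4 and p53 that the study's title names was not tested. The 3 libraries held 17017907, 16964740 and 16581579 reads over 54532 listed genes. A mean of at least 1 FPKM (fragments per kilobase of gene, scaled by library size) was reached by 14011 genes, 11772 of them protein coding. The labels differ on what the libraries hold. The titles give 8, 9 and 10 weeks to replicates 1, 2 and 3, the extraction text names femurs ground to powder, and the characteristics name RAW264.7, a mouse macrophage-like cell line used as a source of osteoclast precursors.

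Xist, the RNA that coats the inactive X chromosome of females, was present at 96.7, 87.1 and 91.0 FPKM in libraries 1, 2 and 3, from 29988, 26341 and 27014 reads. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in all 3 libraries. A count of 0 allows up to 3 reads, or 0.0334 FPKM for Ddx3y and 0.0417 FPKM for Eif2s3y in library 1. The 1570 genes listed on the Y chromosome held 294, 223 and 72 reads in the 3 libraries, of which 270, 202 and 30 fell on Gm47283 near the distal end of the chromosome.

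Transcripts of marrow cells led the libraries. The beta-globin gene Hbb-bs had the highest level, at 23367 ± 3287 FPKM (SD, n = 3), followed by the alpha-globin gene Hba-a1 at 16505 ± 1378. S100a9 and S100a8, the calprotectin genes of neutrophils, stood at 10768 ± 507 and 7216 ± 567 FPKM (SD, n = 3). The 4 adult globin genes together took 3.68% ± 0.432 of all reads (SD, n = 3), and the 19 measured genes of the erythroid list took 4.58% ± 0.487. The neutrophil list took 2.51% ± 0.0708 of reads, the monocyte and macrophage list 0.550% ± 0.00736 and the B cell list 0.448% ± 0.0352 (SD, n = 3). Lyz2, the lysozyme gene of myeloid cells, varied little, at 2786 ± 33.0 FPKM. Genes of T and NK cells took 0.0203% ± 0.00306 of reads and endothelial genes 0.0949% ± 0.00549. Cell cycle genes, with Mki67 at 183 ± 8.17 FPKM, took 0.722% ± 0.0267.

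Bone cell transcripts were also abundant but varied more. The osteoblast list took 1.63% ± 1.17 of reads (SD, n = 3), with Col1a1, the main collagen of bone, at 858 ± 651 FPKM and Bglap, which encodes osteocalcin, at 608 ± 349. The osteoclast list took 0.429% ± 0.0663, with Ctsk, the collagen-degrading protease cathepsin K, at 271 ± 164 FPKM and Acp5, the tartrate-resistant acid phosphatase, at 243 ± 130. The osteocyte list took 0.0572% ± 0.0114, with Sost, the Wnt antagonist sclerostin, at 31.1 ± 6.28 FPKM. Stromal genes took 0.304% ± 0.0197, led by the niche chemokine Cxcl12 at 211 ± 5.10 FPKM, and adipocyte genes took 0.0700% ± 0.0176. A list's share of reads is not the share of its cells, because cells differ in RNA content and a gene with a long transcript gives more reads.

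Of the 3 genes in the study's title, Gpx4 was the most abundant and Trp53 the least. Gpx4, the glutathione peroxidase that reduces lipid peroxides and restrains ferroptosis, stood at 140.6 ± 8.67 FPKM (SD, n = 3). Sat1, the acetyltransferase that starts polyamine breakdown, stood at 63.8 ± 5.56 FPKM, and Trp53, which encodes p53, at 23.0 ± 0.263 FPKM. Within a library Gpx4 was 2.22 ± 0.256 times as high as Sat1 and 6.10 ± 0.413 times as high as Trp53, and Sat1 was 2.77 ± 0.270 times as high as Trp53 (SD, n = 3). These ratios depend on the listed gene lengths, 1724 bases for Gpx4, 2774 for Sat1 and 4045 for Trp53. The SD covers only the spread between libraries. By mean FPKM, Gpx4 ranked 300, Sat1 741 and Trp53 2455 among all genes listed.

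Gpx4 (ENSMUSG00000075706, mm10 chromosome 10, 80047166 to 80056439, plus strand) had 145, 131 and 146 FPKM in libraries 1, 2 and 3, from 4319, 3793 and 4167 reads. These values differed beyond counting noise, with the highest 1.12 times the lowest (chi-square test on reads, Benjamini-Hochberg adjusted p = 3.81e-08). Sat1 (ENSMUSG00000025283, chromosome X, 155213132 to 155216449, minus strand) had 69.3, 63.7 and 58.2 FPKM from 3324, 2978 and 2670 reads, a 1.19-fold range beyond counting noise (chi-square test, adjusted p = 8.24e-12). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) had 22.7, 23.2 and 23.2 FPKM from 1589, 1581 and 1550 reads, with no difference detectable at this depth (chi-square test, adjusted p = 0.999). The exact Poisson 95% interval in library 2 ran from 126 to 135 FPKM for Gpx4, from 61.5 to 66.1 for Sat1 and from 22.1 to 24.4 for Trp53. The table also lists the processed pseudogene Gpx4-ps2, whose reads came to 17.3% ± 1.24 of those of Gpx4 (SD, n = 3), so that part of either count may belong to the other. These chi-square tests compare libraries, not conditions.

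**Figure D1:**
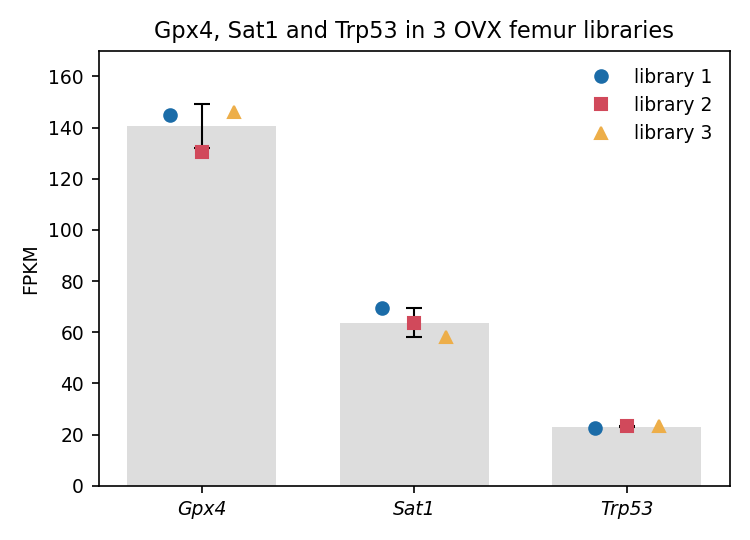
FPKM of Gpx4, Sat1 and Trp53 (vertical axis) in the 3 OVX libraries, where grey bars are means, error bars are SD (n = 3) and the coloured symbols are single libraries. Gpx4 lies between 131 and 146 FPKM, Sat1 between 58.2 and 69.3, and Trp53 between 22.7 and 23.2.

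Genes that promote and genes that restrain ferroptosis, the iron-dependent death by lipid peroxidation, were both expressed in OVX femurs. The promoting list took 0.359% ± 0.0120 of reads and the restraining list 0.461% ± 0.0186 (SD, n = 3). Among promoters, the heme oxygenase Hmox1 stood at 187 ± 23.2 FPKM, the transferrin receptor Tfrc at 130 ± 6.85, the lipoxygenases Alox15 and Alox12 at 38.8 ± 4.83 and 38.5 ± 9.82, and the acyl-CoA synthetase Acsl4 at 9.99 ± 1.05. Among restraining genes the ferritin chains Fth1 and Ftl1 stood at 1635 ± 156 and 575 ± 36.6 FPKM, whereas Slc7a11, the cystine importer, stood at 0.867 ± 0.189 and Aifm2, also named FSP1, at 3.01 ± 0.215. Iron handling genes took 0.454% ± 0.0201 of reads, with the iron exporter Slc40a1 at 37.9 ± 2.77 FPKM. Antioxidant genes took 0.419% ± 0.0204, with the peroxidase Gpx1 at 1252 ± 114 FPKM. Of the tested members, 14 of 23 promoting, 11 of 19 restraining, 13 of 19 iron handling and 11 of 19 antioxidant genes differed between libraries beyond counting noise (chi-square test, adjusted p below 0.05 over all genes). The counts were 14, 11, 14 and 11 when adjusted over the list alone. Over all tested genes 38.6% differed, and the test calls genes with many reads more easily. These lists overlap, so their counts are not separate evidence. Hmox1, Tfrc, Ncoa4, Steap3 and Slc11a2 of the promoting and Fth1, Ftl1 and Slc40a1 of the restraining list also count under iron handling. Nqo1, Gclc, Gclm, Txnrd1 and Slc7a11 of the restraining and Hmox1 of the promoting list also count as antioxidant genes.

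Among targets of p53, the antiproliferative gene Btg2 was the most abundant of those named, at 95.5 ± 3.75 FPKM (SD, n = 3). Bax, which promotes apoptosis, stood at 26.1 ± 1.64 FPKM, Mdm2, the ligase that degrades p53, at 17.0 ± 1.02, and the cell cycle inhibitor Cdkn1a at 7.20 ± 2.25. The list took 0.130% ± 0.00648 of reads. Polyamine genes took 0.238% ± 0.00528, with the synthesis enzyme Odc1 at 155 ± 8.97 FPKM, its inhibitor Oaz1 at 294 ± 5.17, the spermine oxidase Smox at 45.8 ± 2.66 and Sat2 at 0.719 ± 0.117. Between libraries 12 of 24 p53 targets and 8 of 11 polyamine genes differed beyond counting noise by the chi-square test, and 14 and 8 did so when adjusted over the list alone. Over all tested genes the share was 38.6%, and Sat1 is a member of both lists. Cdkn1a was at 5.36, 9.71 and 6.52 FPKM and Gdf15, a stress cytokine, at 5.66, 1.60 and 3.20 in libraries 1, 2 and 3.

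The 3 OVX libraries differed most in genes of cartilage, bone and skeletal muscle. Cartilage genes were highest in library 2, where all 15 tested members of the list were at least 2-fold above the mean of the other libraries on the log2(FPKM + 1) scale. The cartilage collagen Col2a1 had 17.1, 165 and 12.4 FPKM in libraries 1, 2 and 3, the matrix protein Chad 2.96, 188 and 23.1, and the matrix protein Comp 4.17, 73.2 and 14.2. Muscle genes were lowest in library 2 for all 20 tested members, 19 of them at least 2-fold. The muscle actin Acta1 had 441, 28.3 and 299 FPKM, the creatine kinase Ckm 69.7, 4.18 and 43.9, and myoglobin, Mb, 59.8, 1.51 and 52.4.

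Osteoblast genes were highest in library 2 for all 19 tested members, 15 of them at least 2-fold. Col1a1 had 614, 1597 and 364 FPKM in libraries 1, 2 and 3, the matrix protein gene Sparc 447, 1267 and 286, and Ibsp, which encodes bone sialoprotein, 92.1, 305 and 147. Osteoclast genes were lowest in library 1 for 12 of 18 members, with Ctsk at 85.4, 397 and 330 FPKM and Acp5 at 109, 368 and 253. The osteoblast list took 1.17%, 2.95% and 0.760% of reads, with exact 95% binomial intervals from 1.16% to 1.17%, 2.94% to 2.96% and 0.756% to 0.764%. For the chondrocyte list the shares were 0.0692% (0.0680% to 0.0705%), 0.456% (0.453% to 0.460%) and 0.0512% (0.0501% to 0.0523%). For the muscle list they were 0.438% (0.435% to 0.441%), 0.0383% (0.0373% to 0.0392%) and 0.287% (0.284% to 0.289%). The chondrocyte shares in libraries 1 and 3 rested largely on Col11a1 and Col11a2. These genes held 3569 and 5079 of 11780 list reads in library 1, and 1634 and 3124 of 8482 in library 3. The median log2(FPKM + 1) of the tested chondrocyte genes had the other order, at 0.247 in library 1 and 1.14 in library 3.

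The median shift of a list, taken as one library minus the mean of the other 2 on the log2(FPKM + 1) scale, was 4.27 for chondrocyte, 1.43 for osteoblast, 0.69 for osteocyte, 0.44 for adipocyte and 0.37 for osteoclast genes in library 2. It was -2.68 for skeletal muscle, -0.79 for mitochondrially encoded and -0.61 for megakaryocyte genes in that library. In library 1 it was -2.39 for chondrocyte, 1.91 for muscle, -0.53 for osteoblast, -0.46 for osteocyte and -0.41 for osteoclast genes. In library 3 it was -1.41 for chondrocyte, -0.86 for osteoblast, 0.82 for muscle and -0.42 for adipocyte genes. The shifts in libraries 1 and 3 took library 2 as part of their reference. Without library 2, library 3 against library 1 gave 1.56 for chondrocyte, -0.59 for muscle and -0.20 for osteoblast genes, and library 1 against library 3 gave -0.18 for osteocyte and -0.22 for osteoclast genes, so that the sign turned for chondrocyte and muscle genes in library 3 and for osteoblast genes in library 1. The osteoclast shift in library 2 was 0.19 without library 1 and 0.55 without library 3. With a pseudocount of 5 the chondrocyte shift in library 2 was 2.74. Among genes with a mean of at least 5 FPKM the shift was 0.13 for osteocyte and 0.11 for osteoclast genes in library 2, and -0.046 for osteoclast genes in library 1. Each of the shifts over all 3 libraries and tested genes lay outside the central 99% of 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test of a condition. The adipocyte genes Cfd, an adipokine, and Plin1, a lipid droplet protein, stood at 55.1, 184 and 9.25 FPKM and at 1.67, 4.92 and 0.117 FPKM.

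**Figure D2:**
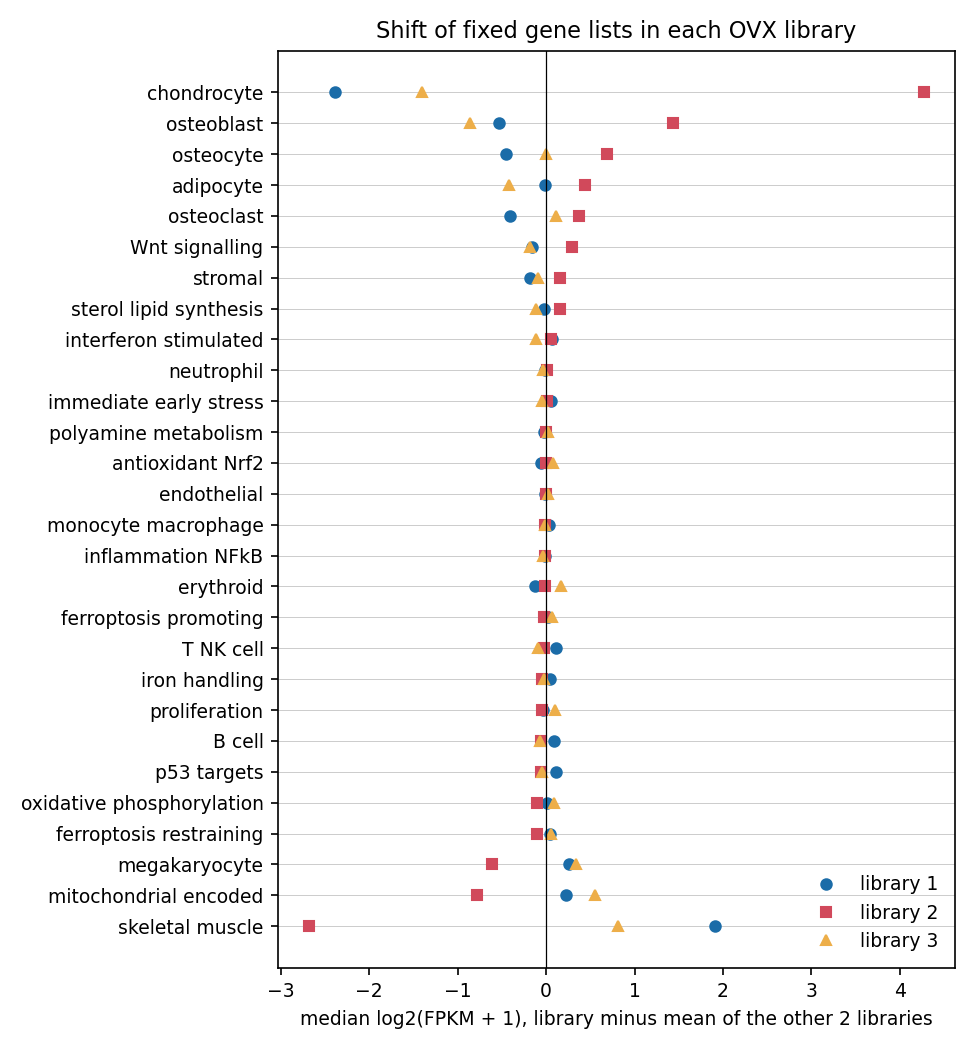
Median shift of each fixed gene list (rows) in each OVX library, as log2(FPKM + 1) in that library minus the mean of the other 2 libraries (horizontal axis). In library 2 the chondrocyte list lies at 4.27 and the skeletal muscle list at -2.68, while the endothelial, neutrophil and macrophage lists lie near 0 in all 3 libraries.

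Most marrow and vessel groups moved far less. In libraries 1, 2 and 3 the shift of the neutrophil list was -0.01, 0.01 and -0.03, that of the macrophage list 0.03, -0.01 and -0.01, and that of the endothelial list -0.02, -0.00 and 0.02. Erythroid genes shifted by -0.13 (-0.078 without library 3), -0.02 and 0.17, B cell genes by 0.09, -0.06 and -0.07 (the last -0.019 without library 1), T and NK cell genes by 0.11, -0.03 and -0.10, stromal genes by -0.19, 0.15 (0.081 at a mean of at least 5 FPKM) and -0.09, and cell cycle genes by -0.04, -0.05 and 0.10. Ferroptosis-promoting genes shifted by 0.03, -0.02 and 0.07 and restraining genes by 0.04, -0.10 and 0.05. The shift of restraining genes in library 2 ranked at percentile 0.33 of the random lists, with 13 of its 19 tested members lowest there. Targets of p53 shifted by 0.11, -0.06 and -0.05, at percentile 99.95 in library 1. There 15 of 24 members were highest and 5, Cdkn1a among them, lowest. The p53 target shift in library 1 was 0.079 with no filter and 0.085 with a pseudocount of 5. Polyamine genes shifted by -0.02, 0.00 and 0.02, iron handling genes by 0.05, -0.04 and -0.02, and antioxidant genes by -0.06, -0.00 and 0.07. Mitochondrially encoded genes shifted by 0.23 and 0.55 and megakaryocyte genes by 0.26 and 0.34 in libraries 1 and 3. Without library 2 the values became -0.21 and 0.21 for mitochondrially encoded and -0.052 and 0.052 for megakaryocyte genes. Of the 29 lists given a shift, 12, 13 and 14 lay outside the central 99% of random lists in libraries 1, 2 and 3, some of them with shifts as small as that of the neutrophil list in library 3.

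**Figure D3:**
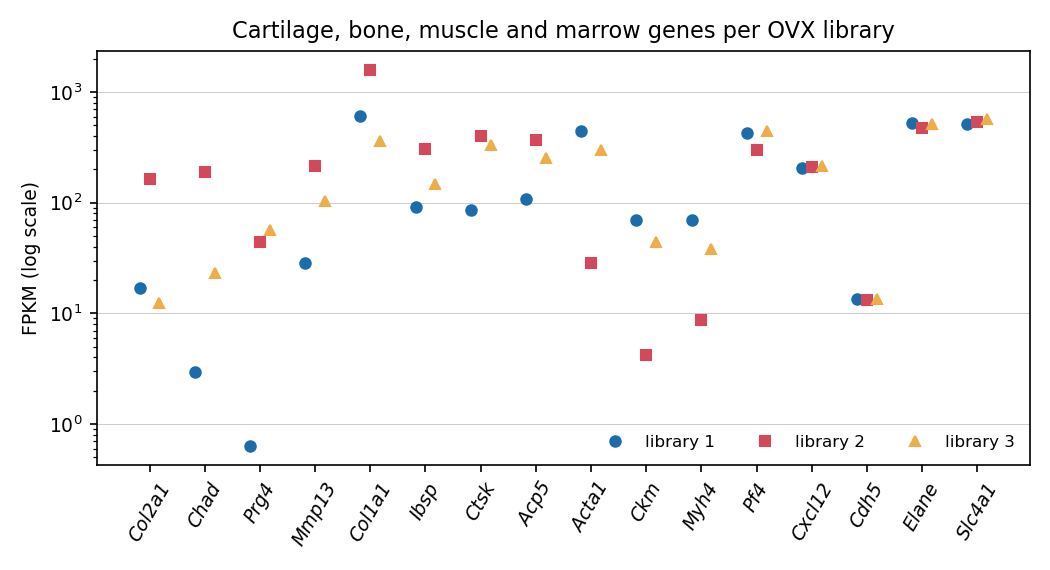
FPKM on a log scale (vertical axis) of 16 cartilage, bone, muscle and marrow genes in each OVX library, 1 symbol per library. Col2a1 has 165 FPKM in library 2 against 17.1 and 12.4 in libraries 1 and 3, and Acta1 has 28.3 against 441 and 299, while Cxcl12 lies between 206 and 216 in all 3.

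Across all 14011 tested genes, 5414 (38.6%) differed between the 3 libraries beyond counting noise (chi-square test on reads, adjusted p below 0.05). At least 2-fold between the highest and lowest library on the log2(FPKM + 1) scale were 825 genes (5.89%), and 267 of the same tested genes without library 2. They were 526 without library 1. Pearson correlations of log2(FPKM + 1) across genes were 0.957 for libraries 1 and 2, 0.980 for 1 and 3, and 0.966 for 2 and 3, where genes are not independent replicates. No pair agreed within sampling noise, with a chi-square per gene of 40.1, 12.1 and 40.9 in the same order, so each library counted as 1 sample. That noise is of read counts alone, so these values do not show that the libraries came from separate animals. The median gene varied by 5.35% (CV) beyond counting noise.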

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

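Except for most settings of the title genes, which were listed beforehand, all alternatives here were chosen after seeing the data. The means of Gpx4, Sat1 and Trp53 moved by less than 1 SD under the other scalings and FPKM from the reads listed. Median-of-ratios scaling could hardly move them, since its factors were 1.0021, 1.0019 and 1.0017 in libraries 1, 2 and 3. The pseudocount and the filter do not enter these means, and a mean of 3 values cannot move by 1 SD when 1 is left out. Without 1 library they ran from 137.8 to 145.6 FPKM for Gpx4, from 61.0 to 66.5 for Sat1 and from 23.0 to 23.2 for Trp53. The count of genes that differed at least 2-fold was 825, and became 1254 with a pseudocount of 0.1, 247 with a pseudocount of 5, and 307 among genes with a mean of at least 5 FPKM. It ran from 278 to 603 with 1 library left out, and from 267 to 596 when the 14011 tested genes were held fixed. The genes kept were 14011, against 27755 with no filter and 8436 at a mean of at least 5 FPKM. In library 2 the shift of the chondrocyte list was 5.91 with a pseudocount of 0.1 and 2.74 with a pseudocount of 5, and 3.64 to 3.97 without 1 other library. With a pseudocount of 5 the shift was 1.26 for osteoblast, -0.56 for megakaryocyte and 0.33 for adipocyte genes, the last also 0.33 at a mean of at least 5 FPKM. Other shifts that this pseudocount moved over 1.5 times became 0.33 for osteocyte, 0.22 for osteoclast, 0.14 for Wnt signalling and 0.079 for sterol and lipid genes in library 2, -1.39 for chondrocyte, -0.28 for osteocyte, -0.23 for osteoclast and -0.092 for Wnt signalling genes in library 1, and 0.059 for osteoclast and -0.11 for Wnt signalling genes in library 3. The osteocyte shift in library 2 was 1.05 with a pseudocount of 0.1, and quantile normalization gave -0.071 for erythroid genes in library 1 and -0.063 for neutrophil genes in library 3. Beyond the damping of low values by a larger pseudocount, the cause was not tested. Of the 39 list shifts outside the central 99% of random lists, the only ones rerun, 7 changed sign with 1 library left out. In library 1 these were osteoblast (-1.33 to 0.20), megakaryocyte (-0.052 to 0.56) and mitochondrially encoded genes (-0.21 to 0.68), and in library 3 chondrocyte (-3.64 to 1.56), muscle (-0.59 to 2.36), Wnt signalling (-0.37 to 0.011) and osteoclast genes (-0.19 to 0.22). The first 6 turned without library 2 and the osteoclast list without library 1, since the library left out was then no longer part of the reference. Without a change of sign, shifts ran from -3.97 to -1.56 for chondrocyte, 0.59 to 3.16 for muscle, -0.75 to -0.18 for osteocyte and -0.33 to -0.011 for Wnt signalling genes in library 1, and from -1.53 to -0.20 for osteoblast, 0.052 to 0.63 for megakaryocyte and 0.21 to 0.89 for mitochondrially encoded genes in library 3. Leaving aside 23 values that could not move by that much, 352 stayed within their spread or within 1.5 times the main count, 63 moved and 7 changed sign. No paired analysis was possible because the columns of the zingerone group could not be matched to labels. The planned fits without a trend, with library weights, a week block or recovered reads, at an adjusted p of 0.1 and with other gene set tests were thus not run. Depth limits low genes most, with Slc7a11 at 211, 158 and 242 reads.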

Other observations

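The tests of gene length, GC content and the joint surface were set after the pattern but before their own values were seen, the comparison of libraries 2 and 3 was added later, and all other tests here only after the values they use had been seen.

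Interferon-stimulated genes took 0.0923% ± 0.00394 of reads (SD, n = 3), with Isg15 at 84.6 ± 4.10 FPKM and the antiviral gene Rsad2 at 61.0 ± 3.97. Their shift was 0.07, 0.05 and -0.12 in libraries 1, 2 and 3, and 12 of 18 tested members were lowest in library 3. Inflammation genes took 0.0588% ± 0.000812, with shifts of -0.01, -0.02 and -0.03 and Tnf at 2.66 ± 0.710 FPKM. Immediate early genes took 0.0704% ± 0.00147, with shifts of 0.05, 0.01 and -0.04. Sterol and lipid synthesis genes took 0.0972% ± 0.0201 and were shifted by -0.03, 0.15 and -0.11, with the desaturase Scd1 at 48.6, 94.9 and 26.8 FPKM. The adipocyte list moved in the same order, by -0.01, 0.44 and -0.42, and a link between the lists was not tested. Wnt signalling genes took 0.0751% ± 0.0102 and were shifted by -0.16, 0.29 and -0.18, the first and last becoming -0.011 and 0.011 without library 2. The osteoblast list shifted by -0.53, 1.43 and -0.86 and the osteocyte list by -0.46, 0.69 and -0.01. Whether the Wnt shift follows the content of bone cells was not tested.

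Platelet genes were lowest in library 2 for all 10 tested members of the megakaryocyte list. The platelet chemokines Ppbp and Pf4 had 875, 558 and 910 FPKM and 428, 301 and 442 FPKM in libraries 1, 2 and 3. Mmp13, the collagenase of hypertrophic cartilage and bone, had 28.8, 214 and 103 FPKM, and Prg4, the lubricin of joint surfaces, 0.635, 44.4 and 56.3. The 4 tested tendon genes went both ways in library 2, with shifts of 1.54 for Fmod, 0.11 for Scx, -0.59 for Tnmd and -0.86 for Thbs4. Col10a1, the collagen of hypertrophic cartilage, rested on 1, 3068 and 136 reads, and Snorc, a cartilage proteoglycan, on 0, 721 and 40 reads. The muscle gene Tnnc2 was listed at 0 in all 3 libraries although Acta1 had up to 441 FPKM, and mt-Co2, mt-Co3 and mt-Atp6 were listed at 205, 71.4 and 48.7 FPKM in library 1 against 6642 for mt-Co1.

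Cartilage and bone genes were higher and muscle genes lower in library 2. One scaling factor, or a smaller share of marrow RNA raising all other tissue alike, is argued against as the whole cause by shifts of the chondrocyte and muscle lists that lay 6.96 apart on the log2 scale. Matching on gene length and GC content left 99.2% of the chondrocyte, 99.1% of the osteoblast and 100.1% of the muscle shift, and a steady trend over the weeks in the titles leaves no room for library 2 outside the other libraries, while 0% of 54 members lay between them, which restates the pattern. An uneven effect of week stays open, with 1 library per week. A candidate explanation is that the piece of femur ground for library 2 held more growth plate, as Mmp13 and Panx3 shifted by a median of 2.55. This list was narrowed to these 2 genes, outside the fixed lists, after a first value had been seen. Mmp13 is also a gene of bone, and all 19 tested osteoblast genes were highest in library 2. The rise of Mmp13 therefore cannot tell growth plate from bone. Panx3 shifted by 3.15 in library 2, from 4, 555 and 19 reads in libraries 1, 2 and 3, and Mmp13 by 1.95. The osteoblast list shifted by 1.43 there. With 2 genes and 1 library, growth plate stays undecided. More joint surface stays undecided too, since its 5 genes shifted by -3.09, 2.23 and 0.65 in libraries 1, 2 and 3. They lay only 0.33 higher in library 2 than in library 3. Neither growth plate nor joint surface accounts for the muscle genes.

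Mitochondrially encoded genes took 2.43%, 1.48% and 2.78% of reads in libraries 1, 2 and 3, with exact 95% intervals from 2.42% to 2.43%, 1.47% to 1.48% and 2.77% to 2.79%, and 12 of 13 were lowest in library 2. Less muscle RNA as the whole cause is argued against by library 3, where the median level of the mitochondrial list was 0.20 above that in library 1 on the log2 scale while that of the muscle list differed by -0.64 (differences of list medians, not medians of gene differences). Genes of nuclear oxidative phosphorylation, which took 0.417% ± 0.0200 of reads, were lowest in library 2 for 22 of 24 members, with shifts of 0.01, -0.10 and 0.09, the last 0.052 without library 2 and 0.14 without library 1. Their shift there was 13.2% of the mitochondrial one, which argues against a matching loss of both sets of transcripts, as fewer mitochondria might bring. A difference in RNA quality or selection was not tested and stays open.

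The labels name both femoral tissue and RAW264.7 cells. Libraries made from RAW264.7 cells alone are argued against by erythroid genes, which took at least 4.15% of reads in every library, and by Col1a1 at 364 FPKM or more. A mixture with such cells was not tested.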
